A study of Mus musculus with 16 samples.

How the data were processed

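Total RNA from frozen liver portions of 16 mice was sequenced as paired-end 100-base reads, 4 mice in each of 4 groups. The groups were taken from the age and experimental group given with each sample: aged mice (102 weeks) without antibiotics, aged mice of the antibiotic groups PAM I and PAM II, and young mice (12 weeks) without antibiotics. The free-text description of the young samples calls them aged, so the title, age and group fields were used for them. The labels give no pairing of mice, no sex, no litter and no cage.

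The deposited files hold raw fragment counts per gene, 1 library per file, with no normalization and no filter on genes. Per the labels, the authors trimmed reads with Trimmomatic 0.38, aligned them to mouse build mm10 with HISAT2 2.1.0 and counted with featureCounts 1.5.0-p2. Per the file headers, exons were summed per gene with the Ensembl release 99 annotation of GRCm38, paired fragments were counted once, and strand setting 1 was used. Of 55471 gene identifiers, 55230 took their symbol and position from GENCODE M21 and 241 had none. Fragments assigned to genes came to between 36968993 and 52090914 per library, and between 20002 and 23644 genes had at least 1 fragment. No pair of libraries was a copy, the closest pair having a root mean square difference of 0.47 in log2 CPM and a Pearson r of 0.988 across genes. Counting intervals and floors in the text cover counting error only, since reads without molecular identifiers are not independent molecules.

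Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 17046, and libraries were scaled by TMM. A single quasi-likelihood model with 1 mean per group was fitted to all 16 libraries with robust dispersions, and the biological coefficient of variation was 27.3%. Contrasts were tested in both directions with the quasi-likelihood F test and no fold threshold, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The 5 contrasts were each antibiotic group against the aged controls, PAM II against PAM I, aged controls against young mice, and the mean of both antibiotic groups against the aged controls. Log2 fold changes are given with the standard error of the fit (SE), and CPM values are TMM-scaled, with the SD over 4 libraries. Where a young library held few or no fragments of a gene, the ratio of the summed counts is given with its exact 95% interval, or a bound against a floor of 3 counts over the group.

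There were 43 gene lists of liver functions, cell types and possible contaminating tissues, written from general knowledge of the liver, and 40 of them had at least 5 measured genes and were tested. Each was tested with limma 3.58.1: camera with a preset correlation of 0.01 between genes, camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. The mean of each list per library was also compared between groups by exact permutation, two-sided, whose smallest p with 4 against 4 libraries is 0.0286. The other 3 lists had 3 or 4 measured genes and were not tested. List counts "adjusted over the list alone" apply the Benjamini-Hochberg step to the members of 1 list.

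The groups, contrasts, lists, main test, naming rule and most alternatives were fixed before the data were examined. The naming rule took, for each contrast, up to 10 genes in each direction with the largest change among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups, leaving out predicted gene models, pseudogenes and immunoglobulin and T cell receptor segments. Where no gene was called it took the 5 with the smallest p among genes passing the same filters on level, overlap and gene type. Genes with larger paralog families are named as uncertain. It also took up to 4 members of each list by p, and 15 genes named in advance, 1 of which is not reported, among them Xist, Cdkn1a, Cdkn2a, Saa1, Ighm, Arntl and Dbp.

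The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter, dispersions without the robust step, DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, a covariate for the clock genes Arntl and Dbp, and leaving out each library in turn. Added after seeing the data were fits without aged control replicate 4 and young replicate 1, aged PAM II against young mice, covariates for the muscle and Kupffer cell lists, and the permutation of list means. A sex term was not run because every library had Y-linked transcripts and almost no Xist. For every contrast the 35 splits of its 8 libraries, or 100 drawn regroupings of the 12 aged libraries, were fitted in the same way. The similarity of the 2 antibiotic effects, which share their controls, was set against 20 simulated datasets with no group difference among aged libraries. In a simulation with 200 changed genes added to libraries of these depths, 66% of the genes changed 2-fold and 20% of those changed 1.5-fold were called for PAM I against the controls, and 76% and 24% for the age contrast. The changed genes had a mean of at least 1 CPM. All genes were drawn independently, without differences between livers that many genes share, so these rates may be too high for the real data.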

Results

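RNA sequencing counts were compared between livers of 16 mice in 4 groups of 4: aged mice (102 weeks) that had received no antibiotics, aged mice of the antibiotic groups PAM I and PAM II, and young mice (12 weeks) without antibiotics. The series title places the exposure in early life, and neither the drugs, the doses nor the meaning of the group names are given with the samples. Fragments assigned to genes came to 39856490 to 47042924 in aged controls, 44532527 to 48706530 in PAM I, 41233838 to 52090914 in PAM II and 36968993 to 42733282 in young mice. The Y-linked gene Ddx3y lay between 16.1 and 44.3 CPM in the 16 libraries and Xist, transcribed from the inactive X chromosome, between 0 and 0.114 CPM. The first principal component of the 500 most variable genes took 48.8% of the variance and separated young livers (34.99 to 51.8) from aged ones (-27.2 to -2.05). The second took 18.5% and divided each aged group.

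Skeletal muscle transcripts and genes with higher expression in female than in male liver set the same 6 aged livers apart. In aged control replicate 2, PAM I replicates 1 and 2, and PAM II replicates 2, 3 and 4 the muscle genes lay 2.27 to 4.98 above the control mean on the log2 scale, and the female-biased genes 0.56 to 1.42 above it. In the other 6 aged livers the muscle genes lay at -0.94 to -0.30 and the female-biased genes at -0.70 to -0.02. Genes of xenobiotic metabolism lay at 0.28 to 0.54 in the first 6 livers and at -0.40 to 0.05 in the others. Cyp2a4, Cyp2b9, Cyp2b13 and some Cyp3a genes are in both lists, so this separation is not independent of that of the female-biased genes. Mitochondrially encoded mRNAs lay at 0.17 to 0.67 in the first 6 livers and at -1.11 to 0.19 in the others. Kupffer cell genes had a mean log2 CPM of 3.73 to 4.64 in the first 6 livers. In the others it was 4.76 to 5.82, except for control replicate 3 with 3.21. Within these sets of 6, female-biased and muscle levels had a Pearson r of 0.517 (permutation p = 0.311, Spearman 0.314, permutation p = 0.564) and -0.435 (permutation p = 0.367, Spearman -0.486, permutation p = 0.356). Adjusted over the 8 relations computed, both of these Pearson r had an adjusted p of 0.806.

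**Figure D1:**
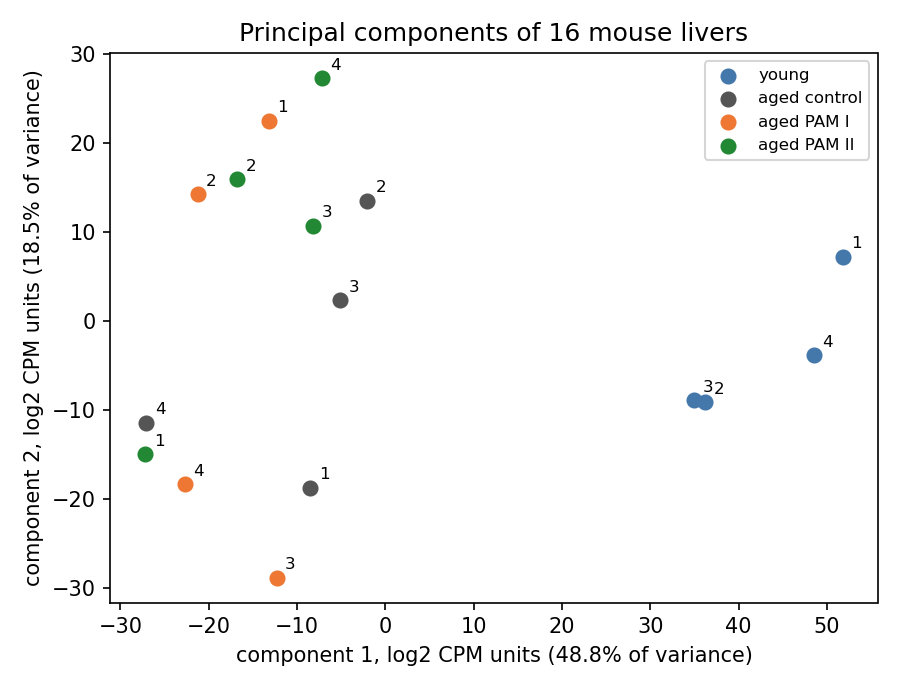
Principal components 1 and 2 of log2 CPM of the 500 most variable genes in 16 livers, 1 point per liver numbered by replicate and coloured by group. Young livers lie at 34.99 to 51.8 on component 1 and aged livers at -27.2 to -2.05, while component 2 divides each aged group.

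The comparison of aged controls with young mice asks what differed in the liver at 102 weeks without antibiotics. Aged livers had far more of several female-biased transcripts and far less of several male-biased ones, although all were read as male. Cyp2b9, a cytochrome P450 of female mouse liver, rose from 0.0511 ± 0.0468 CPM in young to 117 ± 29.8 CPM in aged livers (SD, n = 4 each; log2 fold change 11.04 ± 0.98, adjusted p = 3.56e-05). Its summed counts were 8 and 21394 fragments, a ratio of 2201 with a 95% interval of 1117 to 5098. Hsd3b5, a steroid-metabolizing enzyme of male liver, fell from 215 ± 64.9 to 0.702 ± 0.504 CPM (log2 fold change -8.26 ± 1.02, adjusted p = 0.000406). Selenbp2, a selenium-binding protein with male-biased expression, fell from 529 ± 309 to 9.99 ± 2.79 CPM (log2 fold change -5.73 ± 0.60, adjusted p = 9.14e-05). On GRCm38 (mm10), Cyp2b9 (ENSMUSG00000040660) lies on chromosome 7 from 26173411 to 26210661, Hsd3b5 (ENSMUSG00000038092) on chromosome 3 from 98618634 to 98630252, and Selenbp2 (ENSMUSG00000068877) on chromosome 3 from 94693556 to 94704413.

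Of 24 measured female-biased genes, 12 rose, 0 fell and 12 did not pass, and 16 rose when adjusted over the list alone. Their median log2 fold change was 2.39, which was the same with the members at 0 in young livers set to their bound. Slc22a27, an organic anion transporter, rose by 3.96 ± 0.42 on the log2 scale (adjusted p = 0.000126), and Atp6v0d2, a subunit of the vacuolar proton pump, by 2.43 ± 0.27 (adjusted p = 0.000154). Hao2, a hydroxyacid oxidase, had 6.07 ± 1.20 (adjusted p = 0.013, 0.0529 without young replicate 1, and 0.322 with limma voom). Of 22 male-biased genes, 15 fell, 0 rose and 7 did not pass, 19 fell when adjusted over the list alone, and the median was -1.79. Ces4a, a carboxylesterase, fell by 4.33 ± 0.50 (adjusted p = 0.000237), and Cspg5, a proteoglycan, fell by 4.05 ± 0.64 (adjusted p = 0.00314). Both lists were called by camera (adjusted p = 7.06e-22 and 3.7e-30) and each had an adjusted p = 0.0292 with an estimated correlation.

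Genes of close families may share reads with paralogs, so their single values are uncertain. Among them are Cyp2b9, Hsd3b5, Selenbp2, Ces4a and Slc22a27 above, the Cyp2, Mup and Serpina1 genes here, and further members of these families below. Cyp2a4, Cyp2b13 and also A1bg, a plasma glycoprotein, were higher in aged livers, with log2 fold changes of 5.38 ± 0.86 for Cyp2a4 (adjusted p = 0.00316) and 4.66 ± 1.12 for A1bg (adjusted p = 0.0349). Cyp2b13 had 648 fragments in aged and 0 in young livers, at least 178-fold higher against a floor of 3 counts over the group (adjusted p = 0.0319). Of the major urinary proteins and serine protease inhibitors, Serpina1e fell by 4.12 ± 0.80 on the log2 scale (adjusted p = 0.0112). Mup11 fell by 4.08 ± 0.93 (adjusted p = 0.0275), Mup8 by 3.27 (adjusted p = 0.0346) and Mup16 by 3.02 (adjusted p = 0.0404; lowest 1.77 with 1 library left out). With 1 library left out in turn, Cyp2b13 and A1bg were called in 1 of 8 fits (adjusted p up to 0.09 and 0.118), and Mup8, Mup11 and Mup16 in 3 of 8 (up to 0.123, 0.0865 and 0.177). With limma voom Cyp2a4 had an adjusted p of 0.212, Cyp2b13 0.381 and A1bg 0.309, and without control replicate 4 and young replicate 1 Serpina1e had an adjusted p of 0.0819.

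Genes of lipid storage were higher in aged livers. Cidea, a lipid droplet protein first known from brown fat, rose from 0.0613 to 54.2 ± 34.3 CPM (SD, n = 4; log2 fold change 9.76 ± 0.97, adjusted p = 5.58e-05). Its summed fragments were 9 and 9726, a ratio of 889 with a 95% interval of 468 to 1945. Aged control replicate 1 held 5.04 CPM of Cidea, and limma voom did not call the gene (adjusted p = 0.165). Of 18 lipid droplet genes 7 rose, 0 fell and 11 did not pass, 12 rose when adjusted over the list alone, and the median was 0.77. Cidec, which enlarges lipid droplets, rose by 3.64 ± 0.47, the fatty acid transporter Cd36 by 2.74 ± 0.37 and the triglyceride synthesis enzyme Mogat1 by 3.18 ± 0.51. The list was called by camera (adjusted p = 7.06e-16) and with an estimated correlation (adjusted p = 0.0292). Of 32 PPAR-alpha targets of fatty acid oxidation, 5 rose, 0 fell and 27 did not pass (8 higher and 1 lower adjusted over the list alone, median 0.25). Cyp4a14 rose by 2.34 ± 0.30, Acot2 by 1.86 ± 0.27 and Vnn1 by 1.41 ± 0.27 (adjusted p = 0.0667 without control replicate 4 and young replicate 1). Camera called this list (adjusted p = 4.91e-06), with an adjusted p = 0.433 with an estimated correlation. The lists of cholesterol synthesis (median 0.30, 0 of 24 genes called) and fatty acid synthesis (median 0.37, 0 of 21 called) were called upward by camera (adjusted p = 0.000896 and 0.00335). Each had an adjusted p = 0.471 with an estimated correlation. Without control replicate 2 the fatty acid synthesis list had an adjusted p of 0.0515, without young replicate 2 its median was 0.86, and that of cholesterol synthesis 0.46. Without young replicate 4 the fatty acid synthesis median was 0.22, and without control replicate 3 the PPAR-alpha median was 0.12.

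**Figure D2:**
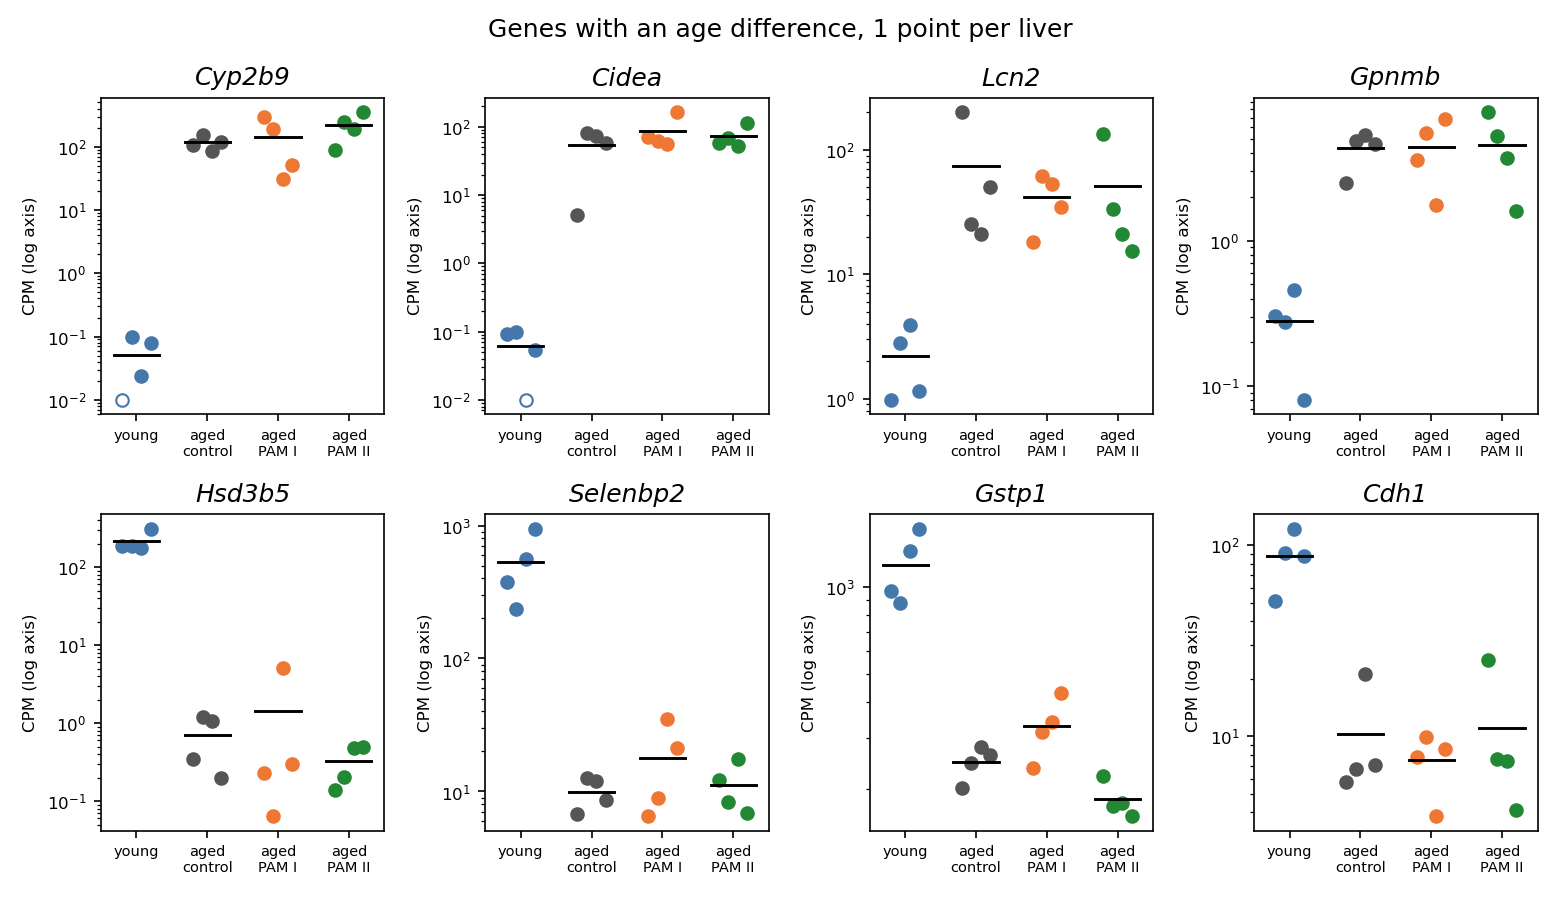
CPM (log axis) of 8 genes with an age difference in each liver, 1 point per liver and a line at the group mean; open circles mark 0 CPM, drawn at 0.01. Cyp2b9 averaged 117 CPM in aged controls and 0.0511 in young livers, and Hsd3b5 averaged 0.702 and 215.

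Some genes of recruited macrophages and inflammation were higher in aged livers. Gpnmb, a protein of lipid-laden macrophages, rose by 3.92 ± 0.57 and Itgax, the integrin CD11c, by 3.01 on the log2 scale (n = 4 each). Of 21 genes of recruited monocytes and lipid-associated macrophages 7 rose, 0 fell and 14 did not pass, 17 rose when adjusted over the list alone, and the median was 1.80. Fry gave an adjusted p = 0.0288 and camera an adjusted p = 0.247 with an estimated correlation. Of 36 inflammation genes 4 rose and 32 did not pass, 17 rose when adjusted over the list alone, and the median was 0.75 (0.50 without control replicate 4). The list had an adjusted p = 0.329 with an estimated correlation and 0.0401 from fry. Tnfaip3, a brake on NF-kappaB, rose by 1.23, and the cytokine Il1b by 2.14 (adjusted p up to 0.0601 without young replicate 4). Without control replicate 4 and young replicate 1 Itgax had an adjusted p of 0.0766, Tnfaip3 0.0638, Il1b 0.0841 and Lcn2 0.0627. Lcn2, an iron-carrier-binding acute phase protein, rose from 2.22 ± 1.41 to 74.1 ± 84.9 CPM (log2 fold change 5.04 ± 0.91, adjusted p = 0.00784). Of 32 acute phase genes 6 rose and 26 did not pass (9 higher and 1 lower adjusted over the list alone; median 0.51, and 0.27 without control replicate 1), with an adjusted p = 0.433 with an estimated correlation. Saa1, a serum amyloid, had 2.62 ± 0.70 (adjusted p = 0.0543). Its value was 1.35 without control replicate 1, and it was called without control replicates 2 or 3 (adjusted p down to 0.0362).

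A few lymphocyte genes were higher in aged livers. Ighm, the immunoglobulin M heavy chain, rose from 17.7 ± 9.51 to 83.5 ± 22.9 CPM (SD, n = 4; log2 fold change 2.24 ± 0.42, adjusted p = 0.0101, and 0.101 without control replicate 4 and young replicate 1). Jchain, which joins immunoglobulin chains, had 2.13 ± 0.62 (adjusted p = 0.0746). Of 31 B cell and plasma cell genes 3 rose and 28 did not pass, and 8 rose when adjusted over the list alone (median 0.99; adjusted p = 0.433 with an estimated correlation). T cell and NK cell genes had 2 of 37 higher, 5 adjusted over the list alone, and a median of 1.15 (adjusted p = 0.471 with an estimated correlation), and the 2 genes, Cd5 and Gzmk, were called in 2 and 3 of 8 fits with 1 library left out. Kupffer cell genes had 0 of 21 called and a median of 0.98 (camera adjusted p = 0.000698, and 0.471 with an estimated correlation). All 37 interferon-gamma response genes had a positive fold change, 1 of them called and 7 adjusted over the list alone, with a median of 0.59 (adjusted p = 0.433 with an estimated correlation). The antigen presentation gene H2-D1 was the 1 called, in 3 of 8 fits with 1 library left out. Interferon-stimulated genes had 1 of 34 higher, Slfn8, called in 2 of 8 such fits, and a median of 0.38 (adjusted p = 0.471 with an estimated correlation). Without control replicate 4 the medians were 0.26 for B cells, 0.28 for T cells (adjusted p = 0.0523), 0.64 for Kupffer cells, 0.16 for the interferon-gamma response and 0.09 for interferon-stimulated genes (adjusted p = 0.349). Without control replicate 1 the Kupffer cell list had 0.68 (adjusted p = 0.052).

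Cell cycle genes, senescence genes and markers of scarring were also called upward by camera. Of 36 cell cycle genes 5 rose and 31 did not pass, 15 rose when adjusted over the list alone, and the median was 0.86 (adjusted p = 0.329 with an estimated correlation, 0.0373 from fry). They included the spindle gene Tpx2 (1.58), Top2a, which untangles DNA (1.95), and the regulator Foxm1 (1.69), each lost in 3 of 8 fits with 1 library left out, among them those without young replicates 1 and 4 (adjusted p up to 0.0943). Of 28 genes of senescence and its secretory products 4 rose and 24 did not pass, 8 adjusted over the list alone, with a median of 0.98 (0.62 without control replicate 4). The 4 were Mmp12, Il1b, Ccl2 and Ptges, the last 2 called in 4 of 8 fits with 1 library left out. Il1b and Ccl2 also count among the inflammation genes that rose, and Mmp12 among those of recruited macrophages. The senescence result is therefore not separate from those lists. The senescence list had an adjusted p = 0.247 with an estimated correlation and 0.0288 from fry. The cell cycle inhibitors Cdkn1a (1.04 ± 0.42, adjusted p = 0.192) and Cdkn2a (0.35, adjusted p = 0.847, and 0.11 to 0.67 with 1 library left out) did not pass. Timp1, an inhibitor of matrix breakdown, had 3.36 (adjusted p = 0.0142, 0.0601 without young replicate 4, and 0.0844 without control replicate 4 and young replicate 1). Of 29 stellate cell genes 2 rose, Timp1 and Ccn2 (called in 3 of 8 fits with 1 library left out), 5 adjusted over the list alone, with a median of 0.52 (0.29 without control replicate 4; adjusted p = 0.433 with an estimated correlation). Of 18 fetal and tumour markers 3 rose, with Ly6d at 3.998 (adjusted p = 0.24 with limma voom), and 2 fell, with Tff3 at -4.38 (adjusted p = 0.0465, -1.96 without young replicate 3, and called in 1 of 8 fits with 1 library left out, up to 0.19, and 0.203 with limma voom). Their median was 0.54 (adjusted p = 0.329 with an estimated correlation). Bile duct genes had 0 of 15 called and a median of 0.59 (adjusted p = 0.471 with an estimated correlation; 0.39 and adjusted p = 0.0839 without control replicate 4, adjusted p = 0.0513 without young replicate 1).

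Single genes of hepatocyte function were lower in aged livers. Gstp1, a glutathione transferase, fell from 1196 ± 331 to 247 ± 33.2 CPM (SD, n = 4; log2 fold change -2.28 ± 0.21, adjusted p = 4.76e-05). Cdh1, the adhesion protein E-cadherin, fell from 88.0 ± 29.0 to 10.2 ± 7.37 CPM (log2 fold change -3.11 ± 0.55, adjusted p = 0.00725). The clotting factor genes F11 (-1.09) and Klkb1 (-0.66) fell with C6 (-1.73, lost in each of the 8 fits that left out 1 library). Klkb1 had an adjusted p of 0.125 in a fit of the 8 libraries alone. Of 34 complement and coagulation genes 3 fell and 31 did not pass, and 7 fell when adjusted over the list alone. Their median was -0.16 (-0.27 without control replicate 1 and -0.06 without control replicate 4; adjusted p = 0.433 with an estimated correlation). Of 27 bile acid genes 3 fell and 24 did not pass, and 6 fell when adjusted over the list alone. Their median was -0.23 (-0.12 without control replicate 1 or young replicate 2, -0.06 without control replicate 4; adjusted p = 0.433 with an estimated correlation). The genes that fell, Amacr, Cyp7b1 and Cyp27a1, were called in 3, 2 and 1 of the 8 fits. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.09 (adjusted p = 0.942; -0.31 to 0.16 with 1 library left out). Of 25 hepatocyte identity genes 1 fell, Serpina1a (adjusted p = 0.0807 in a fit of the 8 libraries alone), and 24 did not pass; the median was -0.23 (-0.15 without young replicate 2), with an adjusted p = 0.247 with an estimated correlation and 0.00837 from fry. Of 23 endothelial genes 2 fell and 21 did not pass, 6 adjusted over the list alone, with a median of -0.47 (-0.30 without control replicate 1; adjusted p = 0.433 with an estimated correlation). The endothelial genes that fell, Dnase1l3 and Clec4g, were called in 2 and 0 of the 8 fits. Of 53 genes of xenobiotic metabolism 6 rose and 5 fell, among them the esterase Ces2a (-1.01), and camera did not call the list (adjusted p = 0.26).

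The remaining lists held few or no called genes. Nuclear-encoded respiratory chain genes had 69 of 74 negative fold changes, 0 called and a median of -0.19 (-0.12 without young replicate 1; adjusted p = 0.433 with an estimated correlation). Amino acid metabolism had 0 of 32 called and a median of -0.33 (adjusted p = 0.435 with an estimated correlation), and ribosomal proteins 0 of 78 and -0.17 (adjusted p = 0.639 with an estimated correlation). Of 22 heat shock and immediate early genes 1 rose and 3 fell, among them Egr1 (-2.51) and Ier2 (-1.10), while Fosb had 2.14 and was lost without young replicate 4 (median -0.19; adjusted p = 0.433 with an estimated correlation). Ier2 had an adjusted p of 0.0837 in a fit of the 8 libraries alone, and Egr1 0.0561 without control replicate 4 and young replicate 1. Red cell genes had a median of -0.85 and muscle genes of -3.52 (each with an adjusted p = 0.471 with an estimated correlation), and muscle genes had -6.49 without control replicate 2 and -1.92 without young replicate 1. Without control replicate 2 or young replicate 1 the ribosomal list was not called (medians -0.08 and -0.04, adjusted p up to 0.0906), and it had -0.26 without control replicate 4. The immediate early list was not called without control replicates 1 or 2 or young replicate 1 (adjusted p up to 0.104) and had -0.29 without control replicate 3. The red cell list was not called without control replicate 1 or young replicates 1 or 2 (adjusted p up to 0.104; -0.53 without young replicate 1). Camera did not call the lists of clock, glucose, zonation, growth hormone, neutrophil, NRF2, endoplasmic reticulum stress, adipose and mitochondrially encoded genes.

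In all, 327 genes rose and 224 fell, 551 of 17046 tested, and 397 of the 551 changed at least 2-fold. Named genes that passed and belong to no group above were Adgrf1, an adhesion receptor (-4.89 ± 0.61, adjusted p = 0.000453), Rad51b, a DNA repair gene (4.57 ± 0.53, adjusted p = 0.000232), and Clec2h, a lectin-like gene (-3.56 ± 0.52, adjusted p = 0.00159). Noct, a clock-regulated gene, rose from 7.90 ± 5.79 to 168 ± 95.2 CPM (n = 4 each; adjusted p = 0.00253). A4gnt, a glycosyltransferase, had 473 fragments in aged and 3 in young livers (ratio 130, 95% interval 44.1 to 631; adjusted p = 0.0179, up to 0.0724 without young replicates 1 or 4, and 0.326 with limma voom). The lipid synthesis genes Srebf1 (0.35, adjusted p = 0.458), Fasn (0.72, adjusted p = 0.447) and Scd1 (0.48, adjusted p = 0.625) did not pass. With 1 library left out they ran from 0.17 to 0.70, 0.45 to 1.52 and 0.14 to 0.90, each highest without young replicate 2 (adjusted p = 0.0617, 0.0583 and 0.313). Neither did Pck1 of glucose synthesis (-0.65, adjusted p = 0.318, and -0.17 without young replicate 1), Ddx3y (adjusted p = 0.812) and the clock genes Arntl (0.06, adjusted p = 0.939) and Dbp (-1.11, adjusted p = 0.548). The sign of Dbp turned without young replicate 1 (0.79), and those of Arntl and Ddx3y also turned when some library was left out. The count was 284 without control replicate 4, 271 without young replicate 1 and 199 without young replicate 4, and 155 without control replicate 4 and young replicate 1, chosen after seeing the data. Young replicate 1 had 13.9% of its fragments from mitochondrial genes (4.14 to 9.01% in the other 15 libraries), the fewest genes with a fragment, 20002, and the lowest TMM factor, 0.887. The count was 1343 with DESeq2 and 486 with limma voom, 298 with the muscle list as covariate and 198 in a fit of the 8 libraries alone. Aged controls and young mice occupied different plate columns. Aged PAM II mice shared the column of the young mice, and this contrast, chosen after seeing the data, had 541 genes higher and 343 lower than in young livers, 435 of the 551 among them in the same direction. It carries the antibiotic group besides age. It also uses the same 4 young libraries, so its overlap with the 551 genes is not independent of them.

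**Figure D3:**
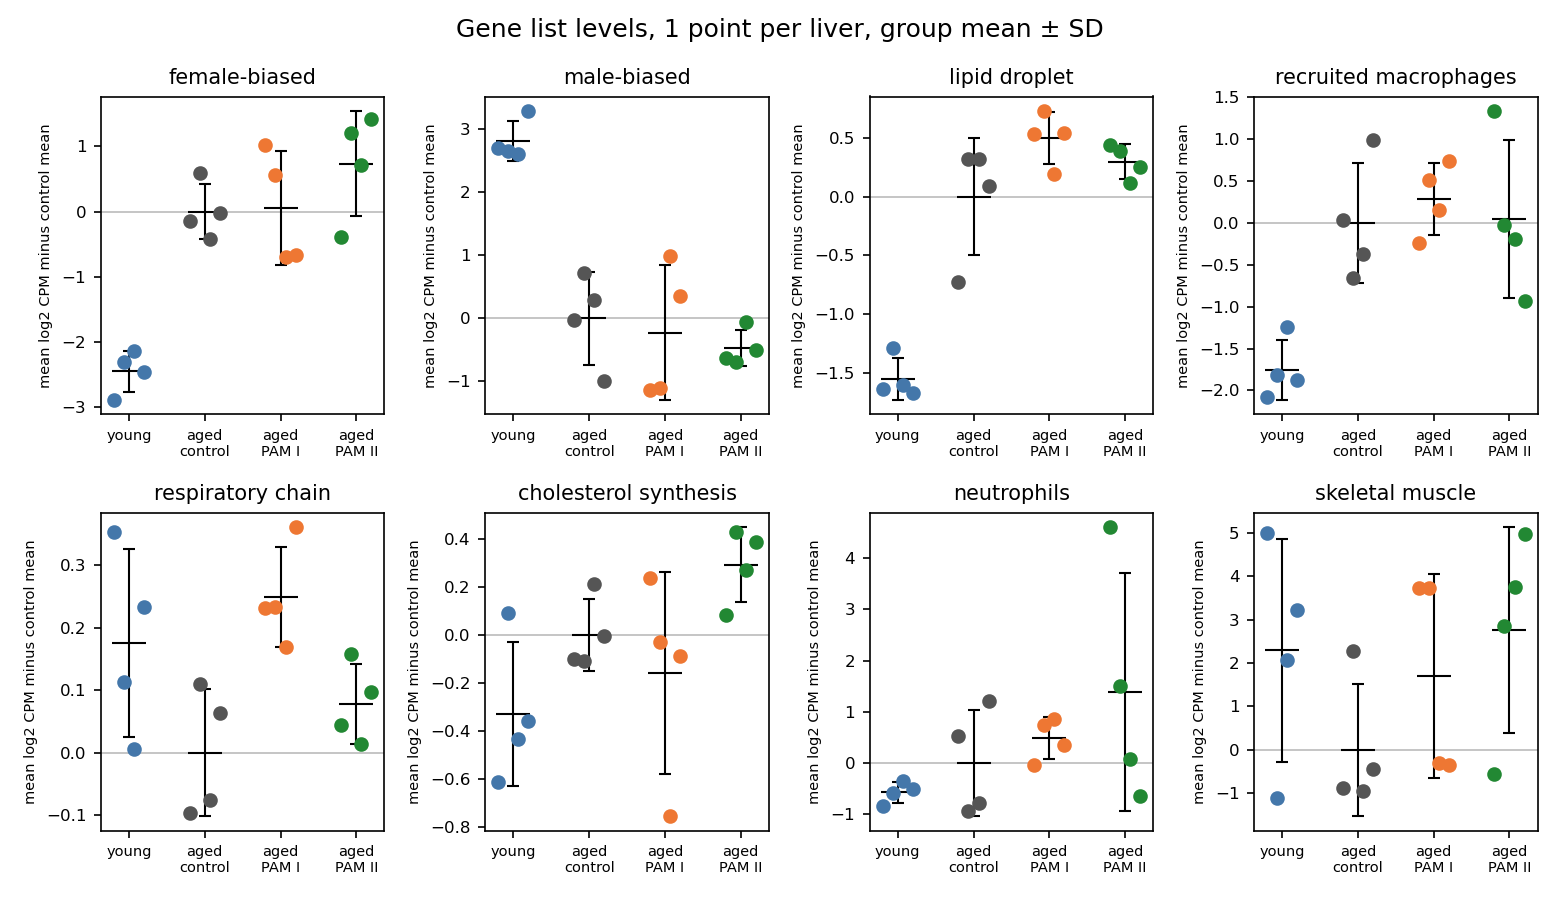
Mean log2 CPM of 8 gene lists in each liver relative to the aged control mean, 1 point per liver, with the group mean ± SD. Female-biased genes lie at -2.89 to -2.15 in young livers and -0.70 to 1.42 in aged ones, and PAM II replicate 1 has 4.604 for neutrophil genes.

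PAM I against aged controls asks whether livers of aged mice of this antibiotic group differed from those of aged mice without antibiotics. No gene passed in edgeR, and the values below are sizes with n = 4 per group. Of the genes that the naming rule admits, Tet3, a DNA demethylation enzyme, had the smallest p, with 15.5 ± 3.61 CPM in PAM I and 27.8 ± 1.55 CPM in controls (log2 fold change -0.84 ± 0.16, adjusted p = 0.506). Alas1, the rate-limiting enzyme of heme synthesis, had 255 ± 42.8 against 123 ± 12.7 CPM (1.06 ± 0.24, adjusted p = 0.506), and Ighm 264 ± 172 against 83.5 ± 22.9 CPM (1.66 ± 0.41, adjusted p = 0.506; lowest 1.10 with 1 library left out). Pcnt, a centrosome gene, had -0.41 ± 0.09, Map1lc3a, of autophagy, 0.51 ± 0.11, and Dop1a -0.65 ± 0.14. DESeq2 called these 6 genes, with an adjusted p of 0.0095 for Tet3 and for Pcnt, 0.0257 for Dop1a, 0.0286 for Map1lc3a, 0.0312 for Alas1 and 0.0388 for Ighm. Tet3 (ENSMUSG00000034832) lies on chromosome 6 from 83362373 to 83459084 and Alas1 (ENSMUSG00000032786) on chromosome 9 from 106233455 to 106248654 of GRCm38.

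Small shifts shared by many genes of a list gave 14 camera calls among 40 lists in PAM I, 12 upward and 2 downward, and 0 calls with an estimated correlation. Respiratory chain genes had a positive fold change in 73 of 74 members, 0 called and 0 adjusted over the list alone, with a median of 0.24. Camera gave an adjusted p = 7.16e-21, and an adjusted p = 0.418 with an estimated correlation. The exact permutation p of the list mean was 0.0286, the smallest that 4 against 4 allows. Of the 40 lists it was the only 1 under 0.05 by permutation. Adjusted over the 40 lists, the smallest permutation p was 0.98. Lipid droplet genes were positive in 18 of 18, with 0 called and 1 adjusted over the list alone, G0s2, an inhibitor of triglyceride breakdown (0.87 ± 0.19), and a median of 0.47 (adjusted p = 0.418 with an estimated correlation). Their median was 0.23 without control replicate 1, whose lipid droplet level was the lowest of the controls. Ribosomal protein genes were positive in 78 of 78 (median 0.19; adjusted p = 0.952 with an estimated correlation), with 0.08 without control replicate 2 and 0.11 without PAM I replicate 4. B cell and plasma cell genes were positive in 30 of 31 and had 1 adjusted over the list alone, Ighm (median 0.75; adjusted p = 0.921 with an estimated correlation). Their median was 0.47 without control replicate 3, 1.41 without control replicate 4 and 0.31 without PAM I replicate 4. Oxidative stress defence genes were positive in 22 of 27, among them Gpx4 (0.49) and Prdx1 (0.34), with a median of 0.31 (adjusted p = 0.418 with an estimated correlation). Heat shock and immediate early genes had a median of 0.26 (adjusted p = 0.757 with an estimated correlation), with 0.13 without control replicate 1, 0.14 without control replicate 2 and 0.16 without PAM I replicate 4.

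The other 8 lists called in PAM I had an adjusted p of 0.952 or 0.953 with an estimated correlation, and each was lost when some library was left out. Upward they were PPAR-alpha targets, xenobiotic metabolism, cell cycle, T cell, Kupffer cell and muscle genes, with medians of 0.18, 0.07, 0.34, 0.28, 0.60 and 2.51. Leaving out 1 library took their adjusted p up to 0.271, 0.41, 0.197, 0.354, 0.369 and 0.0571 in the same order, the last without PAM I replicate 1. Their medians then ran from 0.03 to 0.23, 0.01 to 0.22, 0.07 to 0.47, 0.07 to 1.397, 0.11 to 0.996 and 1.87 to 5.75. Downward they were complement genes (median -0.17, and -0.06 with an adjusted p = 0.341 without control replicate 1) and clock genes (median -0.22, -0.34 to -0.11 with 1 library left out, adjusted p up to 0.148 without control replicate 3). In the clock list Npas2 had -0.89, Cry1 -0.91 and Arntl -0.58 ± 0.27, and Dbp, which is driven by the clock, had 0.91 ± 0.90 (0.58 without PAM I replicate 4, 1.97 without control replicate 4). Control replicates 1 to 4 and PAM I replicates 1 to 4 each ended the call of at least 1 of these lists when left out.

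In edgeR 0 genes passed in PAM I, with 1602 at an unadjusted p under 0.05 where chance gives 852.3. DESeq2 called 16 genes, 10 higher and 6 lower, and limma voom 0, with 1820 and 3252 at an unadjusted p under 0.05. The edgeR number was 1025 without control replicate 3, 3027 without control replicate 4 and 616 without PAM I replicate 4, and 1036 with the clock genes as covariate. Genes named in advance had adjusted p values from 0.506 to 0.993, among them Srebf1 (-0.23), Fasn (-0.02), Scd1 (0.21), Cyp7a1 (0.06), Pck1 (0.07), Cdkn1a (0.02), Cdkn2a (-0.13), Saa1 (-0.95), Jchain (1.67 ± 0.58) and Ddx3y (-0.51). The sign of Saa1 turned without control replicate 1 (0.30), and those of Fasn, Scd1, Cyp7a1, Pck1, Cdkn1a and Cdkn2a also turned when some library was left out. Jchain had 1.09 and Srebf1 -0.13 at their smallest in these fits.

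PAM II against aged controls puts the same question for the other antibiotic group, again with 0 genes called and n = 4 per group. Chka, the choline kinase that starts phosphatidylcholine synthesis, had 86.5 ± 19.4 CPM in PAM II and 176 ± 45.5 CPM in controls (log2 fold change -1.03 ± 0.24, adjusted p = 1). Npas2, a clock transcription factor, had 8.96 against 18.9 CPM (-1.08 ± 0.26, adjusted p = 1) and was the 1 clock gene lower when adjusted over the list alone. Ppp1r9a had -1.41 ± 0.36, Arrdc3 0.63 ± 0.17 and Rictor, of the mTOR complex, -0.69 ± 0.19. Chka (ENSMUSG00000024843) lies on chromosome 19 from 3851773 to 3894369 and Npas2 (ENSMUSG00000026077) on chromosome 1 from 39193731 to 39363236 of GRCm38.

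Camera called 15 of 40 lists in PAM II, 11 upward and 4 downward, and 0 with an estimated correlation. Cholesterol synthesis genes were positive in 23 of 24, with 0 called and 0 adjusted over the list alone, and a median of 0.33. Camera gave an adjusted p = 2.84e-10, and an adjusted p = 0.444 with an estimated correlation, and the exact permutation p of the list mean was 0.0571. Mvk had 0.36 and Tm7sf2 0.37. Endothelial genes were positive in 22 of 23, among them the scavenger receptor Stab2 (0.57) and the clotting protein Vwf (0.71), with a median of 0.30 (adjusted p = 0.444 with an estimated correlation). It was 0.16 without control replicate 1 and 0.52 without control replicate 4. Female-biased genes were positive in 19 of 24 (median 0.59; adjusted p = 0.444 with an estimated correlation). Male-biased genes were negative in 18 of 22 (median -0.34; adjusted p = 0.78 with an estimated correlation; -0.15 and adjusted p = 0.119 without control replicate 2). In the same livers muscle genes had a median of 3.60 (adjusted p = 0.444 with an estimated correlation), and 6.65 without control replicate 2. Endoplasmic reticulum stress genes had -0.21 (adjusted p = 0.454 with an estimated correlation; -0.32 without control replicate 2, -0.16 and adjusted p = 0.0505 without control replicate 3). Interferon-gamma response genes were negative in 34 of 37 (median -0.37; adjusted p = 0.93 with an estimated correlation), and had 0.07 (adjusted p = 0.166) without control replicate 4. T cell genes had -0.54 (adjusted p = 0.972 with an estimated correlation), -0.84 without control replicate 3, 0.48 without control replicate 4, and adjusted p up to 0.588 without PAM II replicates 2 or 4.

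PAM II replicate 1 carried granulocyte and red cell transcripts far above the other livers. S100a9, a neutrophil protein, had 48.6 CPM there and 0.657 to 3.62 CPM in the rest of the group. Slc4a1, the red cell anion exchanger, had 42.6 against 0.235 to 0.609 CPM. Neutrophil genes were positive in 12 of 12, with a median of 3.17 and 7 adjusted over the list alone, and red cell genes in 8 of 10, with a median of 2.07 and 8 adjusted over the list alone. Each list had an adjusted p = 0.444 with an estimated correlation. Without that liver the medians were 0.43 (adjusted p = 0.0672) and 0.23 (adjusted p = 0.325). Kupffer cell genes had a median of 0.48 and B cell genes of 0.26 (adjusted p = 0.848 and 0.93 with an estimated correlation). Without PAM II replicate 1 these were -0.19 and -0.09 and neither list was called (adjusted p = 0.573 and 0.436). They were also lost without control replicate 3 (Kupffer cells, adjusted p = 0.134) and control replicate 1 (B cells, adjusted p = 0.0586), and B cell genes had 1.06 without control replicate 4. Lipid droplet genes had 0.18 (adjusted p = 0.444 with an estimated correlation; 0.05 and an adjusted p = 0.28 without control replicate 1). Respiratory chain genes had 0.06 and xenobiotic genes 0.09 (adjusted p = 0.972 each with an estimated correlation) and were lost when a library was left out. For the respiratory chain these were control replicates 1 and 3 and PAM II replicate 2 (adjusted p up to 0.147), and for xenobiotic genes control replicates 1 and 4 and PAM II replicates 2, 3 and 4 (up to 0.783). Clock genes had a median of 0.16 and a downward camera direction (adjusted p = 0.836).

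In edgeR 465 genes had an unadjusted p under 0.05 in PAM II, fewer than the 852.3 that chance gives, 933 without control replicate 4, and 1047 and 881 with the muscle and Kupffer cell covariates. DESeq2 and limma voom also called 0 genes, with 543 and 902 at an unadjusted p under 0.05. The genes named in advance and reported each had an adjusted p = 1, with Srebf1 at -0.32, Fasn 0.26, Scd1 0.33, Pck1 0.45, Cyp7a1 0.33, Cdkn1a -0.16, Saa1 -1.13, Ighm 0.81, Jchain 0.72, Arntl -0.57, Dbp 1.47, Ddx3y -0.08 and Cdkn2a 1.91 ± 0.70. The sign of Saa1 turned without control replicate 1 (0.13) and that of Jchain without PAM II replicate 1 (-0.03), and those of Cyp7a1, Cdkn1a and Ddx3y also turned when some library was left out. Cdkn2a had 3.46 CPM in PAM II replicate 1 and 0.304 to 0.522 in the rest of the group, and without that liver the log2 fold change was 0.32. With 1 library left out Dbp ran from 1.13 to 2.55, Pck1 from 0.25 to 0.61, Fasn from 0.05 to 0.50 and Scd1 from 0.02 to 0.67. PAM II occupied another plate column than the controls and PAM I, so plate column and group cannot be told apart here or in the comparison with PAM I.

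PAM II against PAM I asks whether the 2 antibiotic groups differed, with n = 4 each. No gene passed. Gstp1, which fell with age, had 184 ± 26.3 CPM in PAM II and 330 ± 80.5 CPM in PAM I (log2 fold change -0.84 ± 0.20, adjusted p = 0.88) and passed when adjusted over the xenobiotic list alone. Apbb2, an amyloid precursor adaptor, had 10.5 against 7.55 CPM (0.48 ± 0.11, adjusted p = 0.88). Pitpnc1, a phospholipid carrier, had 0.50 ± 0.12, Mrpl34 -0.33 ± 0.08 and Nup210 0.42 ± 0.10. Also adjusted over the list alone, Bcl6, a transcriptional repressor, had 1.63 ± 0.41, Il6ra, the interleukin 6 receptor, 0.79 ± 0.20, the clotting factor F11 0.57 ± 0.14 and the chaperone Hspb1 -0.95 ± 0.21. Gstp1 (ENSMUSG00000060803) lies on chromosome 19 from 4035407 to 4037985 and Apbb2 (ENSMUSG00000029207) on chromosome 5 from 66298703 to 66618784 of GRCm38.

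Camera called 18 lists between the antibiotic groups, 7 higher and 11 lower in PAM II, and 0 with an estimated correlation. Cholesterol synthesis genes were positive in 24 of 24 (median 0.38; camera adjusted p = 8.51e-15; adjusted p = 0.663 with an estimated correlation). Respiratory chain genes were negative in 71 of 74 (median -0.20; adjusted p = 0.7 with an estimated correlation; exact permutation p of the list mean 0.0286). No other of the 40 lists had a permutation p under 0.05, and the smallest permutation p adjusted over the lists was 0.762. Ribosomal protein genes were negative in 78 of 78 (median -0.20; adjusted p = 0.7 with an estimated correlation; -0.33 without PAM II replicate 1 and -0.13 without PAM II replicate 4). T cell genes were negative in 34 of 37 (median -0.96; adjusted p = 0.7 with an estimated correlation), and oxidative stress defence genes had -0.22 (adjusted p = 0.663 with an estimated correlation). Endothelial genes had 0.38 (0.23 without PAM II replicate 1) and female-biased genes 0.32 (0.62 without PAM I replicate 1, 0.52 without PAM I replicate 2, 0.55 without PAM II replicate 1), each with an adjusted p = 0.7 with an estimated correlation. Neutrophil genes had 2.75, with 7 adjusted over the list alone, and 0.21 (adjusted p = 0.754) without PAM II replicate 1. Kupffer cell genes had a median of -0.18 with an upward camera direction (adjusted p = 0.931), and xenobiotic genes 0.06 with a downward one (adjusted p = 0.339).

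Of the 18 lists, 9 were called in each of the 8 fits that left out 1 library. The other 9 were each lost in at least 1 of them, among them B cells (-0.48, and 0.00 with an adjusted p = 0.374 without PAM I replicate 4) and male-biased genes (-0.50, and 0.07 with an adjusted p = 0.6 without PAM I replicate 3). In edgeR 0 genes passed and 778 had an unadjusted p under 0.05. That number was 1330 without PAM I replicate 1, 411 and 381 without PAM I replicates 3 and 4, and 1687, 494 and 414 without PAM II replicates 1, 3 and 4. It was 1425 with the clock covariate, 1364 with the Kupffer cell covariate and 1326 in a fit of these 8 libraries alone. DESeq2 and limma voom called 0 genes, with 937 and 2916 at an unadjusted p under 0.05. Cdkn2a had 2.04 between the groups (0.47 without PAM II replicate 1), Ighm -0.85, Arntl 0.01 and Dbp 0.56. With 1 library left out Ighm ran from -1.07 to -0.30, Arntl from -0.20 to 0.13 and Dbp from 0.24 to 0.93.

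The mean of both antibiotic groups against the controls asks what they shared. No gene passed among 8 antibiotic and 4 control livers. Npas2 had a log2 fold change of -0.98 ± 0.22, Rcor3, a transcriptional corepressor, -0.59 ± 0.13, Rictor -0.69 ± 0.16, Tet3 -0.58 ± 0.14 and Chka -0.86 ± 0.20 (adjusted p = 0.86 each). Respiratory chain genes were positive in 74 of 74 (median 0.16; camera adjusted p = 6.1e-15; adjusted p = 0.845 with an estimated correlation; exact permutation p of the list mean 0.0364). Lipid droplet genes were positive in 18 of 18 (median 0.32, and 0.15 without control replicate 1; adjusted p = 0.658 with an estimated correlation; exact permutation p 0.0465). Adjusted over the list alone, 1 of them passed, G0s2 at 0.67. The respiratory chain and lipid droplet lists were the only 2 of 40 with a permutation p under 0.05. Adjusted over the 40 lists, the smallest permutation p was 0.91. B cell genes were positive in 30 of 31 (median 0.57; adjusted p = 0.845 with an estimated correlation; 0.30 without control replicate 3, 0.33 without control replicate 2, 0.34 without control replicate 1 or PAM I replicate 4, 1.22 without control replicate 4). Rcor3 (ENSMUSG00000037395) lies on chromosome 1 from 192098546 to 192138062 of GRCm38. Camera called 19 lists, 15 upward and 4 downward, 0 of them with an estimated correlation and 6 in each of the 12 fits that left out 1 library, and fry called 0. In edgeR 0 genes passed and 961 had an unadjusted p under 0.05, with 638 without control replicate 1, 2138 without control replicate 4 and 1795 with the muscle covariate. DESeq2 and limma voom called 0, with 1141 and 1776 at an unadjusted p under 0.05.

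Across genes, which are not independent replicates, the fold changes of PAM I and PAM II against the same controls had a Pearson r of 0.514 and a Spearman rho of 0.467, and 67.1% had the same sign. Simulated groups with no difference, sharing their controls in the same way, gave 0.499 ± 0.0126 (SD of 20 draws). With separate pairs of controls for each antibiotic group r lay between -0.208 and 0.152. With the shared controls it was 0.298 when PAM II replicate 1 was left out. The difference between the antibiotic groups had a Pearson r of -0.09 and a Spearman rho of 0.04 with the age difference.

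**Figure D4:**
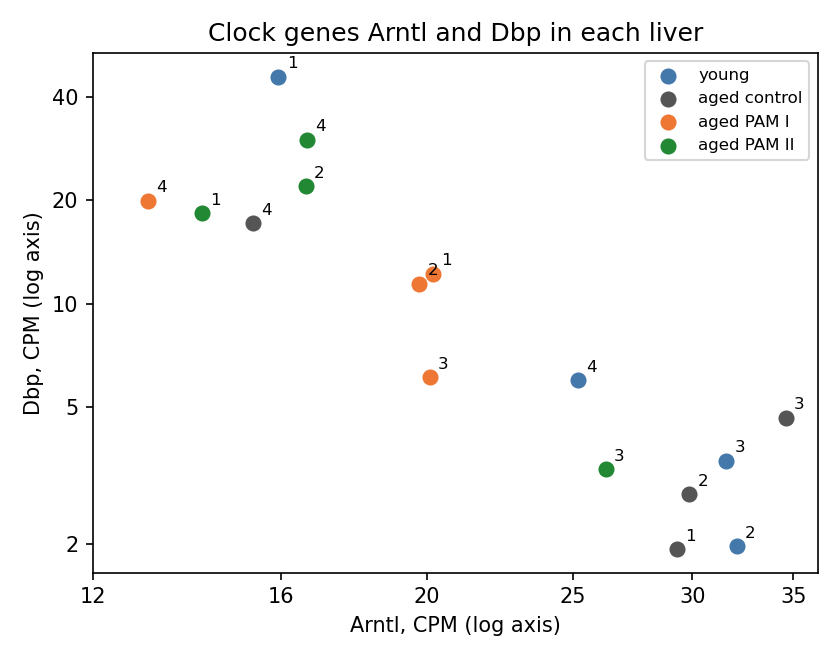
CPM of the clock genes Arntl and Dbp (log axes) in each of 16 livers, 1 point per liver numbered by replicate and coloured by group. Livers with more Arntl had less Dbp, from 1.94 CPM of Dbp in aged control replicate 1 to 45.8 in young replicate 1.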

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

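Of the tests in this part, those on reads shared between paralogs, apart from the medians without Acot and Hsd3b genes, were written before their results were seen, and the others were chosen after. In 371 groups of 4 libraries examined, 22 held a library far from the other 3, and chance gives such a library in about 1 group in 20, or 18.55 groups.

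Female-biased liver genes were higher and male-biased ones lower in aged controls than in young livers, with medians of 2.39 and -1.79. A lower share of hepatocytes would lower both lists, and the rise of the female-biased list by 2.39 argues against it, as the highest Xist of the 4 aged controls, 0.112 CPM before TMM scaling, argues against a female liver among them. Reads shared between close paralogs are argued against by members outside large families, whose medians were 2.34 over 9 female-biased and -1.68 over 10 male-biased genes (1.96 over 8 without Acot and -1.63 over 9 without Hsd3b genes). For the number of genes changed with age, 1 of the 35 splits of these libraries, the real one, gave 551 genes and the highest other split gave 1. Each other split mixes young and aged livers, and 1 in 35 is the smallest share these splits can give. A regrouping of aged livers alone called 500 genes. Chance is therefore argued against for this number but not excluded. Plate column is argued against as the whole cause, since PAM II and young livers shared a column and differed by medians of 2.97 and -2.48, and age itself may account for the pattern and was not tested.

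Clock genes differed between livers within groups, and in all 16 libraries the residuals of Arntl and Dbp around their group means had a Pearson r of -0.878 (permutation p = 1e-05, the smallest they can give) and a Spearman rho of -0.847 (permutation p = 8e-05). Without the 2 libraries farthest in Arntl, r was -0.774. This is what livers taken at different times of day would show, so time of day is a candidate explanation for the spread within groups. The difference of Arntl and Dbp in log2 CPM was 0.49 ± 1.33 (SD, -0.85 to 2.97) in 8 antibiotic livers and 2.50 ± 1.82 (-0.16 to 3.89) in 4 aged controls, with an exact permutation p = 0.0545 over 495 splits. Antibiotic exposure and time of day cannot be told apart for this difference, since collection times are not given and the ranges overlap.

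PAM II replicate 1 stood apart in 6 of the values examined and had high granulocyte, red cell and cell cycle genes. Blood left in the liver portion would bring few transcripts of marrow precursors, and 15 precursor genes lay a median of 5.98 log2 units above the rest of the group, 14 of them highest of the 16 libraries, with Mpo at 23.4, Prtn3 at 35.2 and Ngp at 38.8 CPM. Spleen or lymph node tissue would bring B cell genes, and 8 of these lay a median of 1.02 above the rest of the group (0.53 to 1.47), with 0 of them highest of the 16. The full B cell and plasma cell list also stood apart in this liver (1.41, others of the group 0.03 to 0.22). Blood and such tissue are each argued against as the whole cause, but a part from such tissue is not excluded. Formation of blood cells within this liver may be the source and was not tested, and the design names no biological difference for a single mouse.

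Other libraries stood apart from their group in the mean log2 level of a list relative to the control mean. Lipid droplet genes had -1.29 in young replicate 2 (others -1.67 to -1.61). Bile acid genes had -0.40 in PAM II replicate 1 (0.16 to 0.21), B cell genes 1.41 (0.03 to 0.22), hepatocyte identity genes -0.18 (0.05 to 0.10) and red cell genes 3.36 (-0.12 to 0.37). Interferon-gamma response genes had 0.0351 in PAM II replicate 3 (-0.37 to -0.33). Hepatocyte identity genes had -0.19 in control replicate 4 (0.04 to 0.08). Pericentral genes had 0.32 in PAM I replicate 3 (-0.09 to -0.04) and periportal genes -0.24 (0.03 to 0.08). Male-biased genes had 3.29 in young replicate 4 (2.62 to 2.71), and muscle genes 2.27 in control replicate 2 (-0.94 to -0.45).

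Single genes stood apart in log2 CPM. In PAM I replicate 4, Tet3 had 3.35 (others of the group 4.07 to 4.18) and Arntl 3.71 (4.31 to 4.34). In PAM I replicate 3, Ppp1r9a had 3.39 (1.95 to 2.17). In PAM II replicate 1, Saa1 had 7.65 (5.61 to 5.72) and Clec2h -0.38 (1.17 to 1.22). In aged controls, Cidea had 2.35 in replicate 1 (5.84 to 6.34), Mup11 7.03 in replicate 2 (3.69 to 4.12) and Cdh1 4.41 in replicate 3 (2.53 to 2.84). In young livers, A4gnt had -3.06 in replicate 2 (-4.47), Cyp2a4 -2.10 in replicate 4 (-1.39 to -1.34) and Hsd3b5 8.28 in replicate 4 (7.45 to 7.55). Between the antibiotic groups camera called 18 lists, a direct test of the difference between them, and 0 lists with an estimated correlation.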

How the results depend on the processing

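The alternatives leaving out control replicate 4 with young replicate 1, the covariates for muscle and Kupffer genes and the permutation of list means were chosen after seeing the data. Of 21 named genes called with age, 13 were called in each fit that left out 1 library, 8 of those under each other alternative as well, and 0 changed sign. Lists called in each such fit were 21 of 29 for age, 6 of 14 for PAM I, 4 of 15 for PAM II, 9 of 18 between the antibiotic groups and 6 of 19 for their mean. At these depths 20% of genes changed 1.5-fold and 66% of those changed 2-fold were called in simulated data for PAM I, so smaller changes were largely not detectable. These rates hold for genes of at least 1 CPM drawn independently of each other and may be too high for the real data. A sex term was not run.

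Genes called with age numbered 1343 with DESeq2, 198 in a fit of the 2 groups alone, 298 with the muscle covariate, 155 without control replicate 4 and young replicate 1, and 199 to 573 with 1 library left out. DESeq2 called 16 genes for PAM I. Camera with an estimated correlation called 3 lists for age and 0 in each other contrast, fry 9 and 0, and permutation 0 in all 5 contrasts. With 4 against 4 libraries the permutation p cannot fall below 0.0286. An adjusted p under 0.05 over 40 lists then needs many lists at that floor at once, so the 0 calls of these contrasts carry little weight. That floor does not hold for the mean of the antibiotic groups, with 8 against 4 livers and 495 splits. Its smallest permutation p was 0.0364, or 0.91 adjusted over the lists. The smallest adjusted permutation p for age was 0.0816. With 1 library left out camera called 14 to 22 lists for PAM I (22 without control replicate 4), 15 to 29 for PAM II (29 without its replicate 1) and 12 to 25 for the mean (12 without control replicate 1). The difference between the antibiotic groups had a Pearson r with age of 0.129 over genes of at least 3 log2 CPM, a Spearman rho of 0.202 over them, and a rho of -0.098 to 0.146 with 1 library left out, where r was -0.216 (without PAM II replicate 1) to -0.00323 (without PAM II replicate 4). The r between the 2 antibiotic effects was 0.298 to 0.684 with 1 library left out, and 0.0192, 0.115, 0.0589, 0.152, 0.0665 and -0.208 with the controls divided between them. Fits of fewer libraries have smaller samples, but the count with age was 573 without young replicate 2 against 551 with all libraries. The cause of these changes was not tested.

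With the clock covariate the median reversed for PAM II in complement genes (0.12), B cell genes (-0.0152) and respiratory chain genes (-0.0290), and for the mean in complement genes (0.0383) and ribosomal genes (-0.0281). With 1 library left out the medians that reversed ranged as follows. For PAM I they were interferon-gamma response -0.23 to 0.32 and fatty acid synthesis -0.20 to 0.21. For PAM II they were acute phase -0.24 to 0.16, complement -0.13 to 0.0750, interferon-gamma response -0.50 to 0.0721, T cells -0.84 to 0.48, ribosomal -0.15 to 0.0858, recruited monocytes -0.47 to 0.52, bile duct -0.23 to 0.46, cell cycle -0.12 to 0.32 and mitochondrially encoded mRNAs -0.27 to 0.0848. Between the antibiotic groups they were Kupffer cells -0.77 to 0.16, male-biased genes -0.74 to 0.0658, neutrophils 0.21 to 3.17, where the direction of the test reversed, and red cells -0.77 to 1.48. For the mean they were acute phase -0.27 to 0.15, complement -0.20 to 0.0338, ribosomal -0.00925 to 0.18, amino acid metabolism -0.15 to 0.0808 and interferon-gamma response -0.45 to 0.19. Leaving out control replicate 4 reversed the interferon-gamma response for PAM I, PAM II and their mean. It also reversed T cell and ribosomal genes for PAM II and amino acid metabolism for the mean. Leaving out PAM II replicate 1 reversed recruited monocyte, bile duct, cell cycle and mitochondrially encoded genes for PAM II. Between the antibiotic groups, its absence reversed the Kupffer, neutrophil and red cell lists.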

Other observations

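The simulation of unchanged groups and the splits for the correlation of the antibiotic difference with age were planned, the prediction for these splits being written after. The other tests in this part, splits of the samples, were chosen after the results were seen. Muscle genes were strongly linked across the 16 livers: the 9 muscle genes compared pairwise had a median Pearson r of 0.946 across libraries and a lowest one of 0.839. Young replicates 1, 3 and 4 also had high muscle levels (4.999, 2.07 and 3.22 above the control mean on the log2 scale), and their female-biased genes were low. Genes with a high weight on the second principal component were Myh4, Ckm and Acta1 of muscle together with Cyp2b13, Sult3a1 and Cyp2b9, and on its other side Cd209f, Cd163 and Pf4 of macrophages and platelets with Prtn3 and Slco1a1.

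For PAM I, 35 of the 35 splits of its 8 libraries gave at least its 0 genes (highest other 175), 5 gave as many as its 1602 genes at an unadjusted p under 0.05 (highest other 3656), and 33 gave as many as its 14 lists (highest other 28). For PAM II these were 35 of 35 for 0 genes (highest other 0), 17 for 465 genes at an unadjusted p under 0.05 (3380) and 33 for 15 lists (32). Between the antibiotic groups they were 35 for 0 genes (0), 7 for 778 genes (3530) and 31 for 18 lists (31). For the mean of the antibiotic groups 100 of 100 regroupings gave at least 0 genes (500), 22 gave as many as 961 genes at an unadjusted p under 0.05 (4288) and 71 as many as 19 lists (30). Any split gives at least 0 genes, so the counts of 0 say nothing about chance, and for the counts at an unadjusted p under 0.05 and of lists chance cannot be excluded. With age it cannot be excluded for the 3242 genes at an unadjusted p under 0.05 (4 of 35 splits, highest other 3805) or for the 29 lists (4 of 35, highest other 32).

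The split that called 175 genes set control replicates 1 and 4 and PAM I replicates 3 and 4 against the other 4 libraries, and the regrouping that called 500 genes took PAM I replicates 2, 3 and 4 and PAM II replicate 1 as controls. The next highest regrouping called 31 genes. Splits that call many genes point to a structure of the samples other than the antibiotic groups. The split that called 175 genes parts the livers with high muscle and female-biased levels from others only in part, since control replicate 3 lay low in both. Kupffer cell genes followed this split without overlap, with a mean log2 CPM of 4.76 to 5.71 in the first 4 livers and 3.21 to 4.16 in the other 4.

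For the correlation between the 2 antibiotic effects chance cannot be excluded, as 42 of 100 regroupings gave an r as large as 0.514 (highest other 0.780), and for the correlation of their difference with age 23 of 35 splits gave one as large in size as -0.09 (highest other 0.310). The covariance of the 2 effects was 0.0756 and that of simulated unchanged groups 0.0668 ± 0.00245 (SD, 20 draws), a difference of 0.0088. Of the 100 regroupings 35 gave a covariance as large (highest other 0.184), so chance cannot be excluded for it. Sample weights from limma voom were lowest for young replicate 1 (0.240), control replicate 4 (0.289) and PAM II replicate 1 (0.360) and highest for PAM II replicate 3 (2.94).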
